A study of Aspergillus aculeatus with 24 samples.

How the data were processed

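Aspergillus aculeatus is a filamentous fungus that secretes enzymes that break down plant cell walls. RNA was sequenced from mycelium of 3 strains, BCC56535, BCC199 and HUT2365, grown in a medium with glucose or in a medium with wheat bran and soybean, and collected on day 3 (72 h) and day 6 (144 h). Each of the 12 combinations of strain, medium and day had 2 libraries, labelled as biological replicates A and B, which gave 24 libraries. The labels do not say whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

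Per the labels' protocols, ribosomal RNA was depleted, messenger RNA was enriched, and libraries were made with a kit for Illumina paired-end sequencing on a HiSeq2000. Per the submitters' processing notes, HISAT2 2.1.0, Picard and StringTie were used. Their roles and settings, the genome build, the annotation, the counting tool, the use of strand in counting and the normalization tool are not given in the sources used here. Reads shared between similar genes or overlapping neighbours could therefore not be separated.

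The deposited values are normalized read counts for 8615 gene IDs, a signal that is never negative, with the lowest value at 1 in every library. In each library the deposited value minus 1 was a whole multiple of a single step for 100.0% of the IDs, within 0.02 of a step, so the values behave as whole reads divided by 1 factor per library, plus 1. The steps matched the inverse of median-of-ratios factors of the recovered reads within 0.09%, and the factors ran from 0.67 to 1.27. The recovered reads came to between 19248977 and 30003709 per library. Fold bounds against a group with 0 reads were computed against 3 reads per library, which correspond to 2.37 to 4.48 normalized reads. Where the lower group held 1 to 6 reads, the ratio of normalized reads is given with its 95% exact binomial interval. Bounds and intervals cover counting error only.

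The table gives IDs and no gene names. None of the 8615 IDs matched any of the 11152 genes of the reference table for assembly Aspac1 (0 matches by identifier, locus tag, symbol or accession). The 24 gene lists fixed before the data were examined, cellulose-degrading enzymes among them, therefore matched 0 IDs, and no list was tested. IDs are printed as deposited. The rule for naming them, fixed at the same time, took per comparison at most 2 IDs that rose and 2 that fell, those with the largest changes among IDs past the threshold, with a mean of at least 100 in the higher group and replicates that did not overlap. Each ID has a number prefix and a member number, 8031 prefixes in all. Of the IDs, 1009 share a prefix with at least 1 other ID, and what a prefix stands for is not given in the sources used here.

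For this work, limma 3.58.1 in R 4.3.3 was fitted to log2(deposited value + 1). The 24 libraries entered a single fit with 12 group means, which left 12 residual degrees of freedom, and the variance was moderated with an intensity trend. Comparisons were two-sided contrasts or moderated F tests over 2 contrasts, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. IDs were kept at a deposited value of at least 10 in at least 2 libraries, which kept 8509 and left out 106. Fold changes are on the log2(value + 1) scale and understate the change of low IDs. Means ± SD are over the 2 libraries of a group, in normalized reads with the constant of 1 removed. The test was planned for normalized values, and the deposited values already carry the constant of 1 to which the pseudocount was added.

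The fit was tested on simulated data drawn from the real means and library sizes, with 200 of 8509 IDs changed. For the medium effect of BCC199 on day 3, 67% of 2-fold and 99% of 4-fold changes were called, with 11 unchanged IDs called. For the medium by strain interaction on day 3, 33% of 2-fold and 91% of 4-fold changes were called, also with 11 unchanged IDs called. The simulation gave each ID the same spread in every group, gave IDs of like level the same spread, and held no strain difference. The changed IDs were drawn above a minimum mean and were far fewer than the IDs called in the data. The rates therefore do not cover IDs of low level and may not carry over to the data. In the data the SD of the log2 difference between replicates ran from 0.33 to 0.824 between groups. The simulation therefore does not show how the fit behaves when spreads are unequal.

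Alternatives were a pseudocount of 0.5 or 10, no filter on low values, rescaling by trimmed means of log ratios, quantile normalization, fits with only the libraries of the groups compared, the replicate letter as a block, and each library left out in turn. Voom weights on the recovered reads were added after the data were seen, in place of planned count-model tests that were not run. Tests on the order of the IDs used 1000 shuffled orders. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.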

Results

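The data set held 24 libraries of Aspergillus aculeatus, 2 for each of 12 combinations of 3 strains (BCC56535, BCC199 and HUT2365), 2 media (glucose or wheat bran-soybean) and 2 days (day 3 and day 6). According to the series description, the strains differ in how well they degrade plant biomass and were grown in control and cellulase-inducing conditions. The labels do not say which medium is which, and glucose is taken here as the control. The files do not pair the gene IDs with names, and enzyme activities were not analysed here. Each library held 19248977 to 30003709 recovered reads, and the wheat bran-soybean day 3 replicate B of HUT2365 was the lowest. Between 152 and 245 of the 8615 IDs had 0 reads in a given library, and 7805 had reads in every library. The 10 most abundant IDs took 4.12% to 6.35% of the reads of a library. The closest replicate pair, BCC199 in wheat bran-soybean on day 3, had a median chi-square per ID of 2.05, above the 0.455 that sampling noise alone gives, so no 2 replicates were treated as a single library.

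Strain accounted for 46.6% of the variance of log2 values over the 8509 IDs tested, medium for 23.5% and day for 2.7%. The share of strain includes any fixed difference between strains in how the reads of an ID were counted, from sequence or annotation. The strain by medium term took 13.7%, the terms with day 3.5% (strain by day), 2.2% (medium by day) and 2.8% (all 3 factors), and replicates 5.2%. The first 3 principal components held 25.6%, 23.6% and 21.4% of the variance. BCC199 lay apart from the other strains on the first component, the media parted on the second within each strain, and BCC56535 lay apart from HUT2365 on the third. The SD of the log2 difference between replicates ran from 0.33 (BCC199 in wheat bran-soybean on day 3) to 0.824 (HUT2365 in wheat bran-soybean on day 3).

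**Figure D1:**
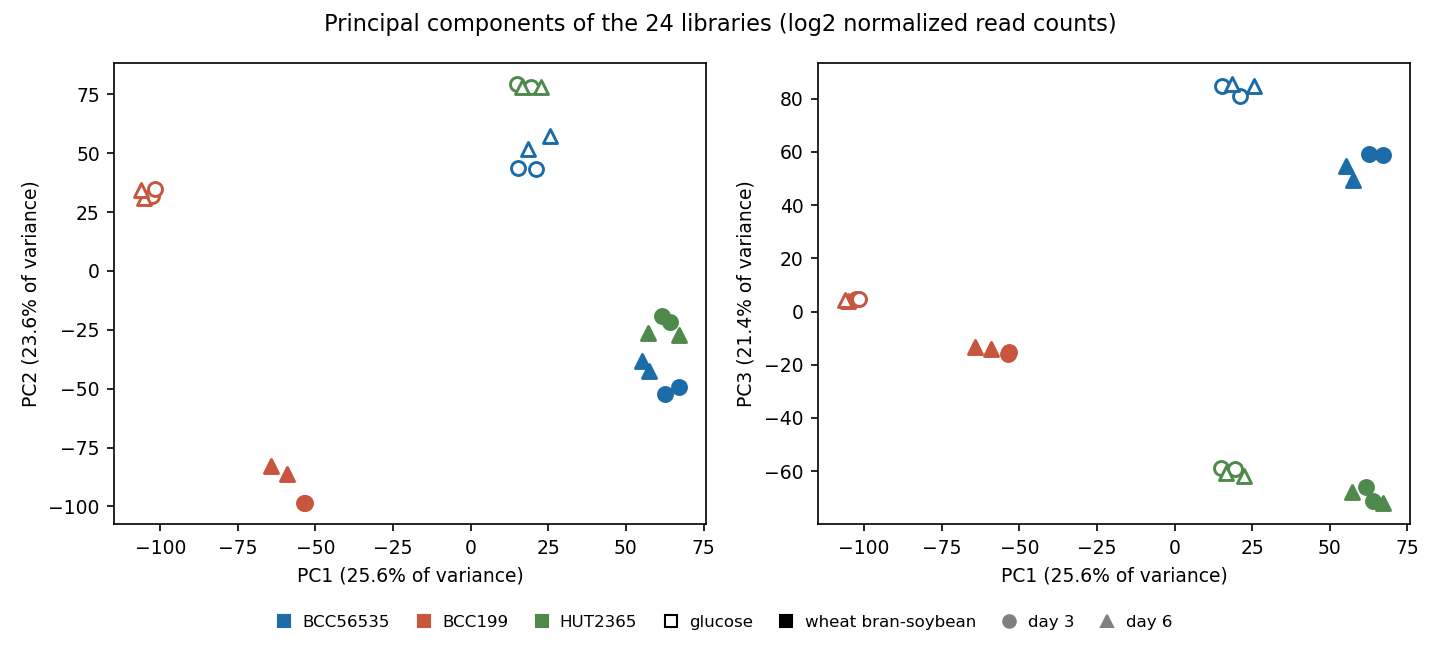
Scores of the 24 libraries on the first principal component against the second (left) and the third (right), with each component's share of the variance on its axis; colour gives the strain, open symbols glucose, filled symbols wheat bran-soybean, circles day 3 and triangles day 6. The 8 BCC199 libraries lie at negative values of the first component, and within each strain the glucose libraries lie above the wheat bran-soybean libraries on the second.

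The first question was what the wheat bran-soybean medium changed in each strain. In BCC56535 on day 3, the largest rises from glucose to wheat bran-soybean, among the IDs that met the naming rule, were those of acu04076_1, from 13.3 ± 9.43 to 26350 ± 21200 normalized reads (SD, n = 2; log2 change 10.63, SE 0.88, adjusted p = 6.5e-08), and of acu05656_1, from 22.3 ± 22.2 to 20110 ± 12000. The largest falls were those of acu02372_1, from 17200 ± 1070 to 9.82 ± 13.9 (log2 change -11.35, SE 0.74, adjusted p = 4.1e-09), and of acu03368_1, from 120600 ± 34600 to 207 ± 278. On day 6 acu05035_1 had 0 reads in glucose and 67470 ± 24800 normalized reads in wheat bran-soybean, at least 20000-fold higher. acu04299_1 rose from 2.22 ± 0.429 to 22310 ± 2490, a ratio of 10200 (interval 3980 to 37400). acu00879_1 fell from 42870 ± 8770 to 0.53 ± 0.75, where it had 1 read (ratio 85900, interval 15400 to 3390000). acu01780_1 fell from 56280 ± 12400 to 3.02 ± 1.27 (6 reads; ratio 18000, interval 8290 to 49200). Of the 8509 IDs, 2059 rose and 2175 fell on day 3, and 1903 rose and 1872 fell on day 6 (limma). Changes of at least 2-fold made up 2967 of the calls on day 3 and 2562 on day 6. With only the libraries of the groups compared, 2780 IDs were called on day 3 and 1849 on day 6, against 4234 and 3775 in the fit of all libraries.

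In BCC199, acu05035_1 led the rises. It had 0 reads in glucose on day 3 and 30730 ± 649 normalized reads in wheat bran-soybean, at least 11200-fold higher (log2 change 13.91, SE 0.47, adjusted p = 1.2e-12). On day 6 it had 1 read in glucose and 50870 ± 6000 normalized reads in wheat bran-soybean, a ratio of 105000 (interval 18800 to 4140000). acu04299_1 rose from 4.61 ± 3.61 to 24060 ± 1330 on day 3, and from 1 read to 28630 ± 5790 normalized reads on day 6 (ratio 58500, interval 10500 to 2310000). On day 3, acu00546_2 fell from 83340 ± 10700 and acu02588_1 from 69140 ± 5870 to 0 reads, which is at least 27900-fold and at least 23300-fold lower. On day 6 the largest falls were those of acu03521_1, from 26810 ± 3110 to 0.585 ± 0.827 (1 read; ratio 47100, interval 8460 to 1860000), and acu00707_1, from 29720 ± 6860 to 1.72 ± 0.879 (3 reads; ratio 17300, interval 5930 to 84100). In all, 2090 IDs were higher and 2255 lower in wheat bran-soybean on day 3, and 1692 were higher and 1823 lower on day 6.

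In HUT2365, acu05035_1 rose from 1 read to 5348 ± 2150 normalized reads on day 3 (ratio 11300, interval 2020 to 445000) and from 2.03 ± 1.6 to 13340 ± 132 on day 6 (5 reads; ratio 6330, interval 2710 to 19500). acu03406_1 rose from 1 read to 4908 ± 1060 on day 3 (ratio 10700, interval 1920 to 424000). On day 6 it rose from 3 reads to 16640 ± 3790 normalized reads, a ratio of 13000 with an interval of 4440 to 62900 (log2 change 12.32, SE 0.56, adjusted p = 6.2e-11). On both days acu03532_1 and acu03368_1 fell most. acu03532_1 went from 77250 ± 12900 to 7.87 ± 3.65 on day 3 and from 82620 ± 14700 to 5.52 ± 0.054 on day 6. acu03368_1 went from 113900 ± 4670 to 17.7 ± 6.09 on day 3 and from 117400 ± 11600 to 29 ± 8.05 on day 6. In all, 2151 IDs were higher and 2080 lower in wheat bran-soybean on day 3, and 1870 were higher and 1888 lower on day 6.

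**Figure D2:**
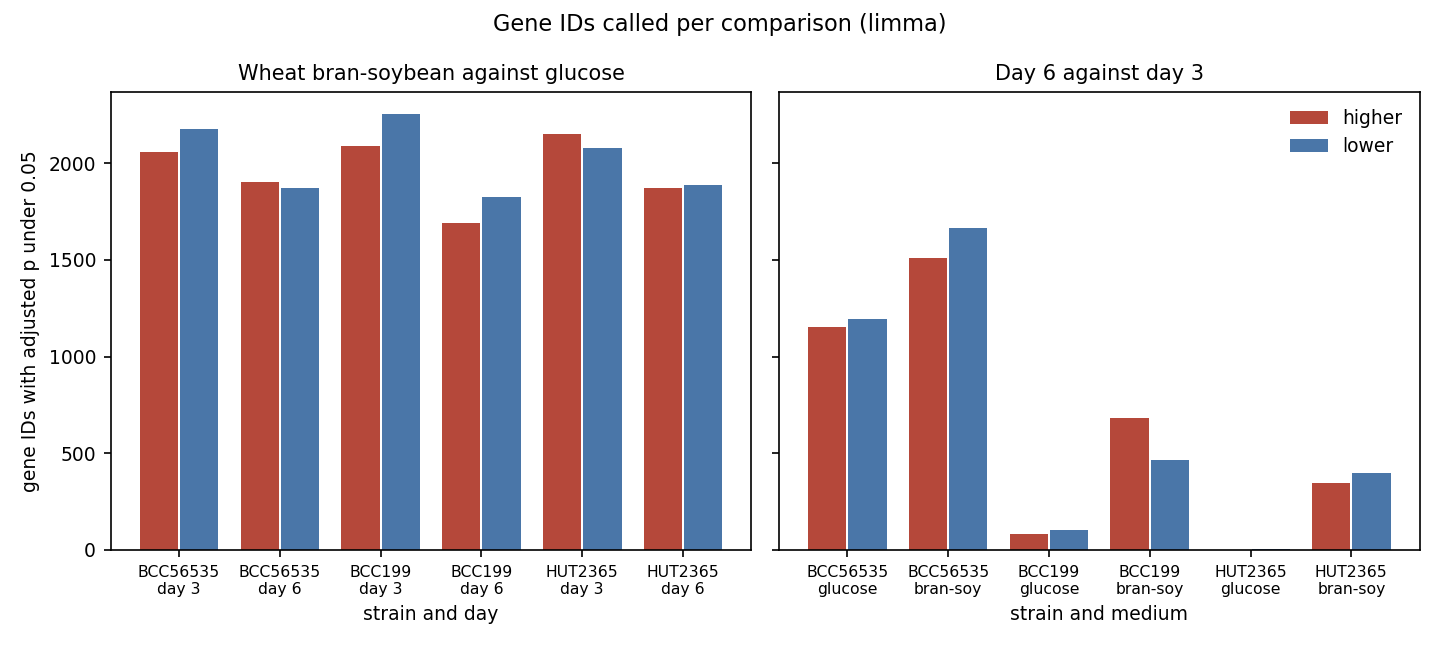
Numbers of gene IDs (vertical axis) with an adjusted p under 0.05 in limma, higher (red) or lower (blue), for wheat bran-soybean against glucose by strain and day (left) and for day 6 against day 3 by strain and medium (right). The medium comparisons called 3515 to 4345 IDs each, whereas the day comparisons ran from 3 (HUT2365 in glucose) to 3170 (BCC56535 in wheat bran-soybean).

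The 6 medium comparisons use different libraries, so their calls were set against each other. They share 1 estimate of the spread per ID, however, so the lists are not fully independent and the expected numbers may be too low. In all 6, 211 IDs were higher in wheat bran-soybean, where independent lists would share 1.2, and 191 were lower, where 1.5 would be shared. acu05035_1 and acu04299_1 were among those higher and acu03368_1, acu03532_1, acu01780_1, acu02588_1 and acu00546_2 among those lower. With only the libraries of the groups compared, and so without a shared spread, the shared sets came to 113 and 127 IDs. No expected number was computed for these. Day 3 and day 6 of a strain also responded alike (correlations below), so the 1.2 and 1.5 do not measure sharing between strains. Over the 3 strains on day 3, 394 IDs were higher, where independent lists would share 127.8, and 382 were lower, where 140.9 would be shared. On day 6, 422 were higher (83.2 for independent lists) and 429 lower (89). Across IDs, which are not independent replicates, the medium effects of day 3 and day 6 correlated at r = 0.605 in BCC56535 (Spearman's rho 0.448), 0.817 in BCC199 (0.736) and 0.885 in HUT2365 (0.818). Between strains on the same day the correlation was lower, from 0.367 to 0.389 on day 3 and from 0.434 to 0.482 on day 6.

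**Figure D3:**
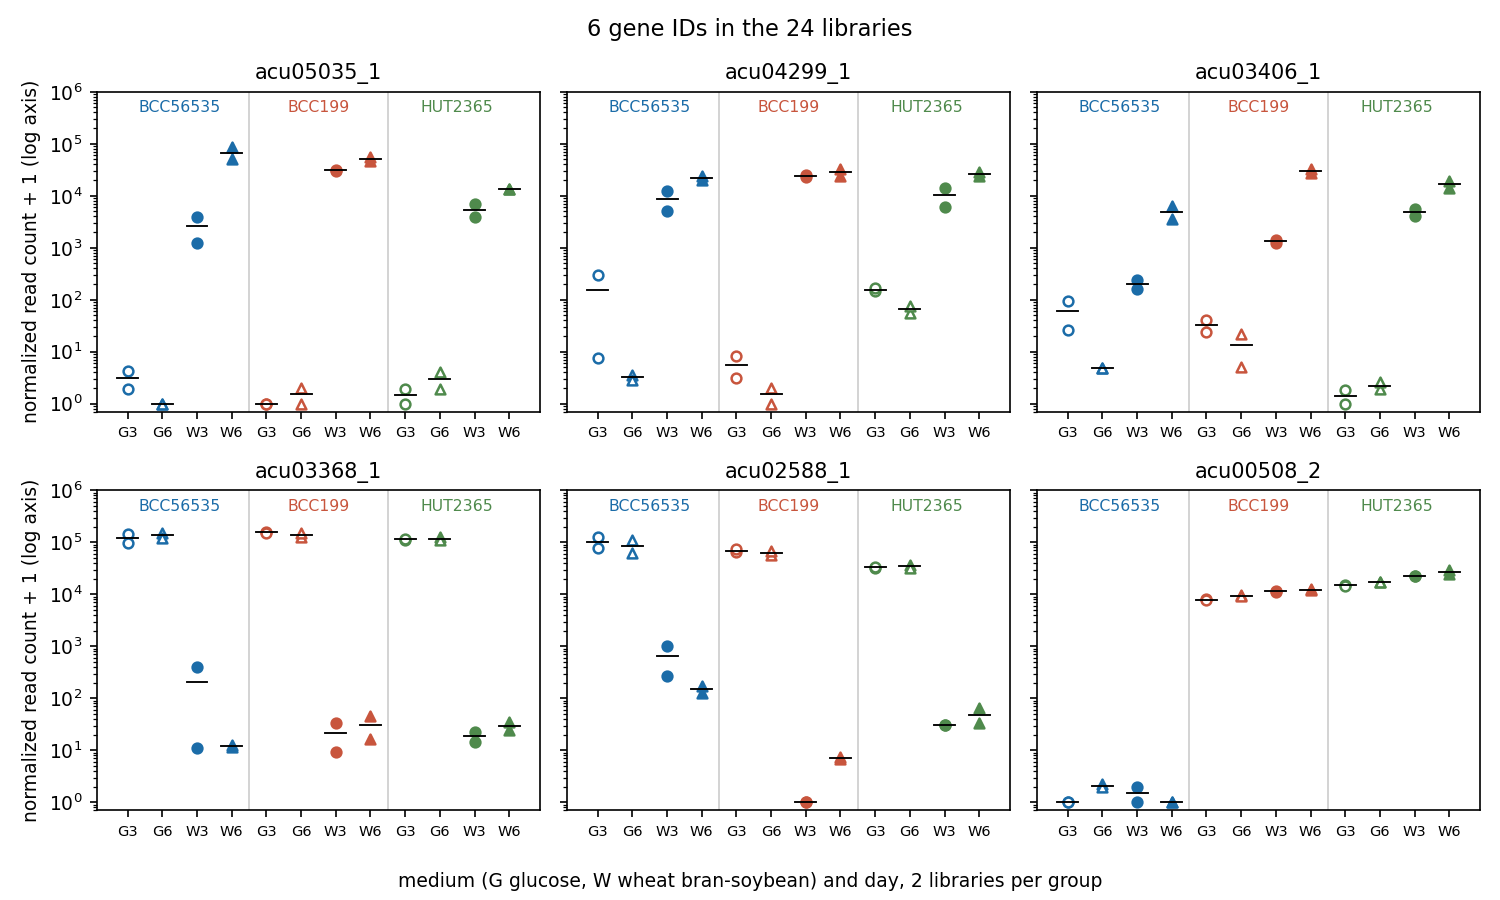
Normalized read count + 1 on a log axis for 6 named IDs in the 24 libraries, by strain, medium (G glucose, W wheat bran-soybean) and day; points are libraries, bars are the means of the 2 libraries, open symbols are glucose and filled symbols wheat bran-soybean. The first 3 IDs are higher in wheat bran-soybean in each strain, the next 2 are lower, and acu00508_2 stays below 10 in the 8 BCC56535 libraries in both media.

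Whether the response to the medium depended on the strain was tested directly. The medium effect differed among the 3 strains for 5650 of 8509 IDs on day 3 and for 4289 on day 6 (moderated F test of the interaction). Between pairs of strains on day 3, it differed for 4023 IDs (BCC56535 against BCC199), 3981 (HUT2365 against BCC199) and 3311 (BCC56535 against HUT2365), and on day 6 for 2438, 2778 and 2810. At least 1 strain called 7224 IDs on day 3, all 3 strains called 1362, and 776 of these changed the same way in the 3 strains. On day 6, at least 1 strain called 6544, all 3 called 1096, and 851 of these changed the same way. Opposite calls in different strains were made for 1538 IDs on day 3 and 800 on day 6. The interaction test called each of these IDs, but it rests on the same estimates and spread, so this is no separate evidence. acu00044_1 was such an ID on day 3: it rose in BCC56535 from 1939 ± 1280 to 19010 ± 2600, and fell in BCC199 from 45930 ± 11700 to 8.38 ± 1.28 and in HUT2365 from 20280 ± 514 to 32.7 ± 36.2 (interaction adjusted p = 3.4e-09). On day 6 it fell in each strain. acu00707_1 had a log2 change of -13.02 in BCC199 on day 3 and of 0.22 in HUT2365 (adjusted p = 0.75; interaction adjusted p = 3.2e-09). In BCC56535 it also fell on day 3, from 24.31 ± 7.55 to 6.818 ± 0.386 (log2 change -1.55, adjusted p = 0.02, limma). In BCC199 it had 5 reads in wheat bran-soybean, a ratio of 13400 with an interval of 5760 to 41400. Its glucose level was 34900 ± 21700 in BCC199 and 144.9 ± 42.1 in HUT2365, from which a fall of that size could not be seen. acu06518_1 rose in BCC199 on day 3 from 3 reads to 9274 ± 4420 normalized reads, a ratio of 7010 with an interval of 2400 to 34000 (interaction adjusted p = 1.4e-08). In wheat bran-soybean on day 3 it had 0 reads in BCC56535 and 5.191 ± 1.11 normalized reads in HUT2365, and its medium effect did not pass in either on that day. On day 6 it also rose in HUT2365, by less than in BCC199 (adjusted p = 0.007 in HUT2365, limma). For acu03368_1, which fell in each strain, the interaction did not pass the threshold (adjusted p = 0.3 on day 3 and 0.64 on day 6).

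The strains were next compared within wheat bran-soybean. acu00508_2 was near 0 in BCC56535 in both media. It had 1 read in wheat bran-soybean on day 3 and 0 on day 6, against 11500 ± 449 and 12370 ± 221 normalized reads in BCC199 and 22510 ± 362 and 27470 ± 3330 in HUT2365. The day 3 ratio was 23600 for BCC199 to BCC56535 (interval 4240 to 933000) and 46400 for HUT2365 to BCC56535 (interval 8340 to 1830000). On day 6 it was at least 4050-fold lower in BCC56535 than in BCC199 and at least 8910-fold lower than in HUT2365. acu00228_1 was low in HUT2365, at 6.92 ± 7.68 on day 3 and 4.31 ± 2.95 on day 6, against 17020 ± 1840 and 15630 ± 4190 in BCC56535. Another ID of the same prefix, acu00228_2, was high in HUT2365 instead, with at least 942 normalized reads in each of its 8 libraries. acu01035_1 was high in BCC56535 on day 3, at 19360 ± 2410, with 3 reads in BCC199 (ratio 13100, interval 4490 to 63600) and 1 read in HUT2365 (ratio 34800, interval 6240 to 1370000). acu00007_9 reached 19730 ± 4120 in BCC56535 on day 6 against 0 reads in BCC199, at least 5840-fold higher. acu06518_1 was high in BCC199, at 9274 ± 4420 on day 3 against 0 reads in BCC56535, at least 3230-fold higher. acu07822_1 stood at 23820 ± 10200 in BCC199 and 4.61 ± 4.03 in HUT2365 on day 3 (log2 difference -11.89, SE 1.06, adjusted p = 1e-07). acu00558_2 was high in HUT2365, at 9326 ± 5130 on day 3 against 0 reads in BCC199, at least 2840-fold higher. For acu00508_2, acu00007_9, acu00558_2 and acu00546_2 above, reads could be shared with other IDs of the prefix, and this was not tested.

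BCC56535 differed from BCC199 in 5251 IDs on day 3 (2703 higher and 2548 lower in BCC56535) and 4681 on day 6 (2341 and 2340). HUT2365 differed from BCC199 in 5348 IDs on day 3 (2760 higher and 2588 lower in HUT2365) and 4830 on day 6 (2454 and 2376). BCC56535 differed from HUT2365 in 4731 IDs on day 3 (2401 higher and 2330 lower in BCC56535) and 4448 on day 6 (2209 and 2239). In glucose, the F test over the 3 strains called 6255 IDs on day 3 and 6430 on day 6. These counts, and the single IDs above, could also reflect a fixed difference between strains in how the reads of an ID were counted. The genome used for each strain is not given, and this was not tested.

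In the fit of all libraries, each change from day 3 to day 6 called fewer IDs than any of the medium comparisons. The order turned in fits of only the libraries compared for BCC199 in wheat bran-soybean, whose day effect called 3295 IDs against 2780 and 1849 for the medium effect of BCC56535 on day 3 and day 6. In BCC56535 in glucose, acu07069_1 rose from 23.7 ± 24.2 to 2864 ± 392 normalized reads, and acu04379_1 fell from 9395 ± 1770 to 34.7 ± 13.4 (log2 change -8.04, SE 1.11, adjusted p = 8.8e-05). In wheat bran-soybean acu04733_1 rose from 3 ± 2.92 to 1688 ± 1280 (6 reads; ratio 566, interval 260 to 1540) and acu02488_1 fell from 2445 ± 626 to 18.1 ± 6.16. In glucose 1153 IDs rose and 1192 fell, and in wheat bran-soybean 1507 rose and 1663 fell. With only the libraries compared, 130 IDs were called in glucose and 1840 in wheat bran-soybean, and the 4 IDs named here still passed. They do not speak for all IDs that the naming rule gave. In glucose it also gave acu01714_1 (766 ± 755 in the higher group) and acu06764_1 (1161 ± 1440). In wheat bran-soybean it also gave acu07849_1 (3712 ± 5050 in the higher group) and acu03460_1 (2378 ± 1270). Without the wheat bran-soybean day 3 replicate B, 2033 were called in wheat bran-soybean.

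In BCC199 in glucose, acu03394_1 rose from 32.4 ± 41.4 to 1244 ± 817, and acu07860_1 fell from 180 ± 19 to 22.5 ± 3.22 (log2 change -2.89, SE 0.3, adjusted p = 0.00029). In wheat bran-soybean acu07846_1 rose from 3.47 ± 0.935 to 1491 ± 51.6, and acu07232_1 fell from 2364 ± 981 to 1.1 ± 1.55 (2 reads; ratio 2120, interval 586 to 17500). Of the 185 IDs called in glucose, 80 rose, and in wheat bran-soybean 682 rose and 466 fell. With only the libraries compared, limma called 0 IDs in glucose, so neither ID named for glucose passed, with 1067 at an unadjusted p under 0.05 (voom weights on all libraries called 215), and 3295 in wheat bran-soybean. In glucose 279 were called without the day 3 replicate B, 57 without the day 6 replicate A and 16 without the day 6 replicate B, and in wheat bran-soybean 560 to 638 without any 1 of the 4 libraries.

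In HUT2365, 3 IDs fell and 0 rose between the days in glucose, and 94 had an unadjusted p under 0.05. The 3 were acu04706_1, from 1442 ± 805 to 15.9 ± 15.8 (log2 change -6.57, SE 0.9, adjusted p = 0.0065), acu05710_1, from 254 ± 110 to 11.7 ± 2.48, and acu06929_1, with a log2 change of -2.89 (SE 0.43, adjusted p = 0.0115), which lay outside the naming rule and was picked once its value was known. With voom weights 2 IDs were called, and acu04706_1 no longer passed (adjusted p = 0.38). In wheat bran-soybean, 346 IDs rose and 400 fell. acu02321_1 rose (log2 change 6.53, SE 0.63, adjusted p = 2.2e-05), and acu00168_3 fell from 2397 ± 465 to 114 ± 22.8 (log2 change -4.37, SE 0.31, adjusted p = 1.3e-06). With only the libraries compared, limma called 0 IDs in either medium, so no ID named here passed, with 488 in glucose and 1397 in wheat bran-soybean at an unadjusted p under 0.05 (voom weights on all libraries called 776 in wheat bran-soybean). Without the day 6 replicate A or B, 335 and 281 were called in wheat bran-soybean, and in glucose 1 was called without the day 3 or the day 6 replicate B.

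The day effect differed among the strains for 1289 IDs in glucose and 2331 in wheat bran-soybean (moderated F test), and for 777 in glucose with only the libraries compared. In wheat bran-soybean, 58 IDs rose from day 3 to day 6 in all 3 strains, where independent lists would share 4.9, and 49 fell in all 3, where 4.3 would be shared. Both sets held 0 IDs in fits of only the libraries compared, since limma then called 0 in HUT2365, with 1397 at an unadjusted p under 0.05.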

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

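The tests below were chosen after the results were seen, except the other splits of the HUT2365 glucose libraries, whose bound was set before that test was run, when the correlations among those libraries had been seen.

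The effect of the medium differed between strains by the interaction test, for 5650 IDs on day 3 and 4289 on day 6. A fixed ratio between strains in how the reads of an ID were counted would cancel in a medium effect, except where reads are few. Yet 70.6% of the 4395 IDs with means of at least 1000 over all libraries and 100 in each strain were called on day 3. These means run over both media, so an ID could still have few reads in a group. No single library accounts for the day 3 count, which was 5019 at its lowest with 1 library left out, and quantile normalization in place of the authors' scaling gave 5713. What made the medium effects differ was not tested. A biological difference between the strains stays open, and so do counting differences other than a fixed ratio, such as shared reads. Culture or processing conditions that varied with the group stay open too, since the labels give no batch.

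The change between days also differed between strains by the interaction test, for 1289 IDs in glucose and 2331 in wheat bran-soybean, and in glucose the day effect called 2345 IDs in BCC56535, 185 in BCC199 and 3 in HUT2365. With only the libraries compared, the interaction called 777 IDs in glucose and 2362 in wheat bran-soybean. The day effect in glucose then called 130 in BCC56535, 0 in BCC199 and 0 in HUT2365. The replicate differences of HUT2365 were not wider than those of BCC56535: their SD was 0.417 on day 3 and 0.407 on day 6, below 0.803 and 0.716. The fit used 1 spread per ID for all groups. It can therefore call too many IDs where replicates differ more, and too few where they differ less. Unequal spreads may have added to the order of the counts, and these SDs cannot decide why the counts differ. If exchanged day labels hid a change as large as that of BCC199, another split of the 4 libraries should have given at least 185 IDs, and the other 2 splits gave 3 and 0 (limma; 246 and 21 at an unadjusted p under 0.05, against 94 for the labelled days). A library entered under both days would differ by sampling noise alone (median chi-square 0.455), and the closest day 3 and day 6 libraries, day 3 replicate A and day 6 replicate B, had 3.492, which is below the 5.615 and 8.247 of the replicate pairs. An exchange that hides a smaller change stays open, since the A minus B differences of the 2 days correlated at -0.485, the lowest of the 66 pairs of groups, and so do a small change of HUT2365 between the days and a whole group with a wrong label or another time of collection.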

How the results depend on the processing

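The voom weights, and every alternative for the pairwise and day by strain interactions and the shared medium response, were chosen after seeing the data. Each alternative was run on 32 counts of IDs. With a pseudocount of 0.5 or 10, no filter, trimmed-mean rescaling, quantile normalization or voom weights, 0 of the 32 moved by over 1.5 times. Over the 66 pairs of groups, the A minus B differences correlated at -0.485 to 0.229 (median 0.015), above 0.1 in 12. The replicate letters thus showed no pairing over the groups as a whole. Among the groups of BCC56535 the correlations ran from -0.013 to 0.225, so a weak pairing within a strain stays open. The replicate block moved 0 of 32 counts by over 1.5 times (4348 IDs for the medium effect of BCC199 on day 3, against 4345).

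Fits with only the libraries of the groups compared moved 11 of 32 counts, 10 down and 1 up (BCC199 day effect in wheat bran-soybean). Such a fit of 2 groups left 2 residual degrees of freedom, against 12 in the fit of all libraries. It also estimated its own spread. A lost call there can therefore reflect less power as well as a different spread. The medium effect of BCC56535 called 2780 IDs on day 3 and 1849 on day 6 (4234 and 3775 as reported). The day effect called 130 in glucose and 1840 in wheat bran-soybean in BCC56535, 0 and 3295 in BCC199, and 0 and 0 in HUT2365 (as reported 2345, 3170, 185, 1148, 3 and 746). The day by strain interaction in glucose called 777 (1289), and the shared medium response held 113 IDs higher and 127 lower (211 and 191). Leaving out 1 library, with the remaining library assumed to vary like the other groups, moved 12 of 228 counts. The day effect then called 2033 to 2705 IDs in BCC56535 in wheat bran-soybean (lowest without day 3 replicate B), 16 to 279 in BCC199 in glucose (16 and 57 without day 6 replicates B and A, 279 without day 3 replicate B), and 560 to 638 in BCC199 in wheat bran-soybean (any of the 4 libraries). It called 1 to 3 in HUT2365 in glucose (1 without replicate B of either day) and 281 to 599 in HUT2365 in wheat bran-soybean (281 and 335 without day 6 replicates B and A). The medium, strain and interaction counts stayed within 1.5 times in these leave-one-out fits. Of the 70 named changes, 12 lost significance with only the libraries compared, each a day effect, and 2 with voom weights (acu07849_1, acu04706_1), and 0 reversed under the alternatives other than leaving out a library, which was not run on single IDs. The cause was not tested.

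Tests by edgeR and DESeq2 were planned in case whole reads could be recovered. Values that behave as whole reads were recovered, so this condition was met, but the tests were not run. The voom fit on the recovered reads stands in their place (4314 IDs for the medium effect of BCC199 on day 3). The cellulose list and the set tests were not run because 0 IDs matched a list. Depth limits the IDs with few reads, whose folds are lower bounds or carry wide intervals.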

Other observations

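All tests in this part were chosen after the data were seen.

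Some IDs followed the strain whatever the medium and day. acu00508_2 stayed below 10 normalized reads in the 8 BCC56535 libraries and at 7710 or more in the other 16, and 3 IDs (acu00370_2, acu01389_1 and acu07091_1) stayed below 10 in BCC199 with at least 138 elsewhere. At 100 or more in each library of a single strain and below 10 in all others were 2 IDs in BCC56535 (acu05611_1 and acu07636_1), 6 in BCC199 and 4 in HUT2365. acu04610_1, of the 6, ranged from 117 to 7751 in BCC199. These IDs were picked by level, once their values were known. Whether a fixed difference between strains in how their reads were counted made them low or high was not tested.

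Whether IDs that share a number prefix part by strain more often than other IDs was not shown. The 425 prefixes with more than 1 ID all had numbers up to 572, while prefix numbers reached 8295. In 6 of the 865 pairs within a prefix, the strain means differed in opposite directions by over 32-fold (2.2 on average and 8 at most over 1000 shuffled assignments of IDs to prefixes; permutation p = 0.026). Over the 8 libraries of a strain, acu00228_1 averaged 15510 ± 3550 normalized reads (SD) in BCC56535, 8464 ± 465 in BCC199 and 6.417 ± 3.96 in HUT2365, while acu00228_2 averaged 0.3638 ± 0.714, 0.6413 ± 0.774 and 1386 ± 473. acu00538_1 averaged 587.6 ± 348 in BCC56535 and 36830 ± 12800 in HUT2365, while acu00538_2 averaged 42530 ± 21600 and 767.9 ± 500. The limit of 32-fold was picked after the values were seen. In 3 of the 6 pairs, 2 of which share acu00011_3, the libraries of the strains overlapped in at least 1 ID. The 3 pairs without overlap were not more than shuffled assignments gave (1.3 on average, 5 at most; permutation p = 0.15).

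IDs with neighbouring numbers changed together. With each strain's mean removed, the mean correlation between adjacent IDs over the 24 libraries was 0.124, where 1000 shuffled orders gave at most 0.015. Reads shared within a prefix are not the cause, since IDs alone in their prefix had 0.128, and overlap of adjacent genes is not the whole cause, since IDs 3 places apart still had 0.031 (shuffled orders at most 0.012). The correlation fell to -0.004 at 50 places. ID numbers that follow gene order along a genome would give this, a hypothesis that no coordinates were used to check. Other local groupings of IDs would give it too. Gene order alone would not put all prefixes with more than 1 ID at numbers up to 572 of 8295. Overlap may still add to the value of direct neighbours.

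Runs of at least 5 consecutive IDs that passed the threshold in the same direction with at least 2-fold changes were found 10 to 25 times per medium comparison, against a mean of 0.9 to 2.5 and at most 8 in shuffled orders (permutation p = 0.001 in each of the 6, the smallest that 1000 shuffles can give). The runs were counted over all IDs, those that share a prefix included. Reads shared within a prefix could therefore add runs, and the count was not repeated on IDs alone in their prefix. The 18 other comparisons with a direction were run too, and no p was adjusted over them. The 6 strain comparisons held 11 to 34 runs (shuffled means 2.7 to 9.2), and 5 of them exceeded every shuffled order. The exception was BCC56535 against HUT2365 on day 3, with 11 runs, a shuffled highest of 13 and a permutation p of 0.009. The 6 pairwise interactions held 6 to 17 (shuffled means 0.4 to 4.9), each above every shuffled order. Of the 6 day comparisons, which held 0 to 8, 1 exceeded every shuffled order and 4 had a permutation p of at least 0.05, 3 of them with 0 runs in the data and in every shuffled order. The longest run of the medium comparisons, 11 IDs from acu02503_1 to acu02515_1, was higher in wheat bran-soybean in BCC199 on day 3 (median log2 change 3.52) and again in the separate libraries of day 6 (2.97). These 11 were singled out because they rose in BCC199, so tests of their difference from the other strains are tilted by that choice and are not used here. In BCC56535 5 of the 11 rose and 5 fell on day 3, and in HUT2365 6 rose.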
